A study of Homo sapiens with 6 samples.

How the data were processed

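Total RNA of 6 samples of PrEC, an immortalized line of normal prostate epithelial cells, was labelled with biotin and hybridised to 1 array each, per the labels' protocols. Samples were grouped by their titles into shNT and shPKCi, with 3 samples each, and the series design text calls them biological replicates. Cells were grown in prostate epithelial growth medium and collected 48 hours after plating, per the labels' protocols. The deposited values are probe set intensities on a linear scale, above 0 throughout, for 32321 probe sets. RMA, which corrects background, quantile-normalizes probes and summarises them per probe set, is named by the submitters' processing notes. Its version, the software and the genome build were not given in the sources used here. RMA returns log2 values by default, so a conversion back to the linear scale was inferred from the values. No detection calls were used here, and the signal level of a dim gene cannot be told from background. Array signal compresses differences of dim and very bright probe sets, so that folds at either end can be understated.

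The intensities were first transformed to log2, as the design had foreseen for a linear table. Gene names came from the platform annotation given with the arrays. That table listed 19158 probe sets with 1 gene symbol, 1388 with several and did not list 11775. Of the first, 19128 had an Entrez identifier in an NCBI RefSeq gene table, and 0 symbols needed an update. Probe sets with 1 symbol were kept, and where a gene had more than 1 (637 of 18404 genes) the probe set with the highest mean was used. Control probe sets could not be told by name, and the requirement of 1 gene symbol left out any probe set without a listed gene. A comparison of 3-prime with 5-prime control probe sets was therefore not run. No genomic coordinates are given, because no build was named. No filter on low values was applied.

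Genes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with all 6 arrays in 1 fit and no covariate. P-values were adjusted by Benjamini-Hochberg over the 18404 genes, with a threshold of 0.05. The median standard error of a log2 fold change was 0.11, with 5.52 prior degrees of freedom. Genes with an unadjusted p under 0.05 numbered 5473. In group differences of array medians, interquartile ranges and 99th percentiles, two-sided exact permutation tests gave p = 0.4, 1 and 0.5, where 0.1 is the smallest p that 3 arrays against 3 allow.

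The 22 gene lists held 474 places, of which 433 had a measured gene. They were serine synthesis and one-carbon folate; methionine cycle, SAM and polyamines; ATF4 and integrated stress response; cytosolic aminoacyl-tRNA synthetases; DNA methylation and Polycomb; neuroendocrine markers; aPKC polarity complex; and other protein kinase C and PKN isoforms. Further lists covered basal and luminal prostate epithelium, squamous differentiation, mesenchymal, fibroblast and EMT genes, endothelial and blood cell markers, cell cycle and DNA replication, glycolysis, hypoxia, and sterol and fatty acid synthesis. The remaining lists were interferon response, NF-kappaB and inflammatory cytokines, YAP and TEAD targets, p53 targets, and endoplasmic reticulum chaperones. Each list was tested two-sided with limma camera, which compares its members with all other genes, at a preset correlation between genes of 0.01, and adjusted over the lists. List members shared between lists count in each. The median of each list was also ranked among 10000 random lists of the same size matched on mean signal in 50 bins.

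The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took PRKCI and PRKCZ, and the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between groups, leaving out XIST and Y-linked genes. It also took 19 genes of serine, methionine, stress, DNA methylation and neuroendocrine biology whatever their values, up to 4 members with the smallest adjusted p of each list past the threshold, and up to 4 more from the serine, methionine, ATF4 and neuroendocrine lists. The rule named 98 genes. Any other gene was named after its values were seen.

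The alternatives were a replicate block, each array left out in turn, median centring, cyclic loess, filters at the median and lower quartile of signal, and other choices among the probe sets of a gene. Others were a trended robust variance, array weights, stricter thresholds including treat against a fold of 1.5, and camera with an estimated correlation, camera on ranks and fry for the lists. After the data were seen, lists without shared members, removal of each array's smooth intensity trend and counts of list members without shNT replicate 2 were added, as were 17 further gene lists, 14 of them defined by symbol pattern.

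The fit was tested on 20 simulated data sets with the 18404 genes, 6 arrays and each gene's spread as estimated by eBayes, in which 200 genes had known changes. For shPKCi against shNT it recovered 6.6% of genes changed 1.25-fold, 69.5% of those changed 1.5-fold, 99.5% of those changed 2-fold and 100% of those changed 3-fold, and 5.75% of calls were false. A list shifted by 0.5 log2 units was called in 100% of simulations and unshifted lists in 0%. Genes were simulated independently of one another, so that these rates do not cover lists of correlated genes such as those measured. Only 200 genes were changed per simulation, whereas 3406 passed the threshold in the data, and the adjusted threshold depends on that number. Every simulated array also had the same spread, whereas shNT replicate 2 deviated more than the others. The recovery rates of genes therefore need not hold for the measured arrays. Tables were handled with pandas 2.3.3 and numpy 2.4.6 and figures drawn with matplotlib 3.10.9.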

Results

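RNA from PrEC, an immortalized line of normal prostate epithelial cells, was measured on 6 expression arrays. The RNA of 3 samples came from cells carrying the hairpin named shNT, which served as the reference group, and the other 3 came from cells carrying a hairpin against PKCλ/ι, written shPKCi here. PKCλ/ι is an atypical protein kinase C encoded by PRKCI, known for its part in epithelial cell polarity. Cells were collected 48 hours after plating with no further treatment. The series describes the 3 samples of each line as biological replicates, and their number limits the precision of every value. The arrays gave values for 18404 named genes. Median intensities were 45.7, 48.6 and 45.1 in shNT replicates 1 to 3, and 44.9, 45.7 and 45.5 in shPKCi replicates 1 to 3. The array of shNT replicate 2 stood apart: its correlation with the other arrays ran from 0.975 to 0.985, against 0.984 to 0.994 among the other 5. Its interquartile range of log2 values was 3.33, and those of the other arrays lay between 3.46 and 3.52. The series title links PKCλ/ι deficiency to serine and one-carbon metabolism and to neuroendocrine prostate cancer, and the single comparison, shPKCi against shNT, addresses which transcripts differ between the lines.

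The transcript that the hairpin targets was lower in every shPKCi array. PRKCI (probe set 8083854, its only probe set) had intensities of 1635, 1428 and 1843 in the shNT arrays and of 800.3, 810.2 and 753.8 in the shPKCi arrays. The group means were 1635 ± 207 and 788 ± 30.1 (SD, n = 3). The log2 fold change of PRKCI was -1.05 (SE 0.11, limma adjusted p = 0.000279), or 2.06-fold lower from the means of log2 values. PRKCZ, which encodes the other atypical isoform, fell by 0.54 on the log2 scale (SE 0.09, adjusted p = 0.00269), or 1.46-fold. Its mean log2 signal was 7.24 ± 0.02 in shNT and 6.70 ± 0.05 in shPKCi (SD, n = 3).

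The largest rises in shPKCi included genes for a calcium-binding protein, a collagenase and a chemokine. CALB1, encoding calbindin, was 7.61-fold higher, at 4.48 ± 0.21 log2 units in shNT and 7.41 ± 0.05 in shPKCi (SD, n = 3; adjusted p = 1.62e-06). NAV3 was 6.87-fold higher, the neutrophil chemokine gene CXCL5 6.55-fold, the interstitial collagenase gene MMP1 5.55-fold and the long non-coding RNA UCA1 4.94-fold. KYNU, a gene of tryptophan breakdown, rose 4.66-fold and the amino acid transporter gene SLC6A14 rose 4.37-fold. SPRR2E, a cornified envelope gene, rose 3.97-fold, the glutathione peroxidase gene GPX2 3.85-fold, and CYP24A1, which encodes the enzyme that inactivates vitamin D, 3.79-fold. CASP14, a caspase gene of epidermal differentiation, was 29.2-fold lower, at 9.81 ± 0.40 in shNT and 4.94 ± 0.58 in shPKCi (SD, n = 3; adjusted p = 7.71e-06). The glucose transporter gene SLC2A3 was 17.2-fold lower, NDRG1 9.64-fold lower, the inositol phosphatase gene INPP5D 9.33-fold lower and the lysyl oxidase gene LOX 8.63-fold lower. The serpin genes SERPINB3 and SERPINB13 were 7.50-fold and 6.07-fold lower, TMEM45A 7.15-fold lower, the complement factor gene CFB 6.09-fold lower and the stress protein gene NUPR1 5.98-fold lower. The adjusted p-values of these 20 genes lay at or below 2.32e-05.

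Across all genes, 1758 were higher and 1648 lower in shPKCi at an adjusted p under 0.05, together 18.5% of those tested. Of these, 135 were at least 2-fold higher and 237 at least 2-fold lower. The groups did not overlap in 6574 genes, or 35.7%, where chance gives 10%. The median log2 fold change of all genes was -0.02. With each array centred on its median, 2170 genes were higher and 1321 lower. The totals moved with the arrays used: 1072 genes were higher and 1057 lower without shPKCi replicate 1, and 997 and 1048 without shPKCi replicate 2; without shPKCi replicate 3, 1165 were higher and 1191 lower. The numbers were 1480 and 1257 without shNT replicate 1, 1935 and 1959 without shNT replicate 2, and 1399 and 1245 without shNT replicate 3. CFB has 2 further probe sets, with log2 fold changes of -2.01 and 0.12, the last at low signal with an SE of 0.77. SERPINB3, SPRR2E and CXCL5 have close relatives whose transcripts can bind the same probes.

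**Figure D1:**
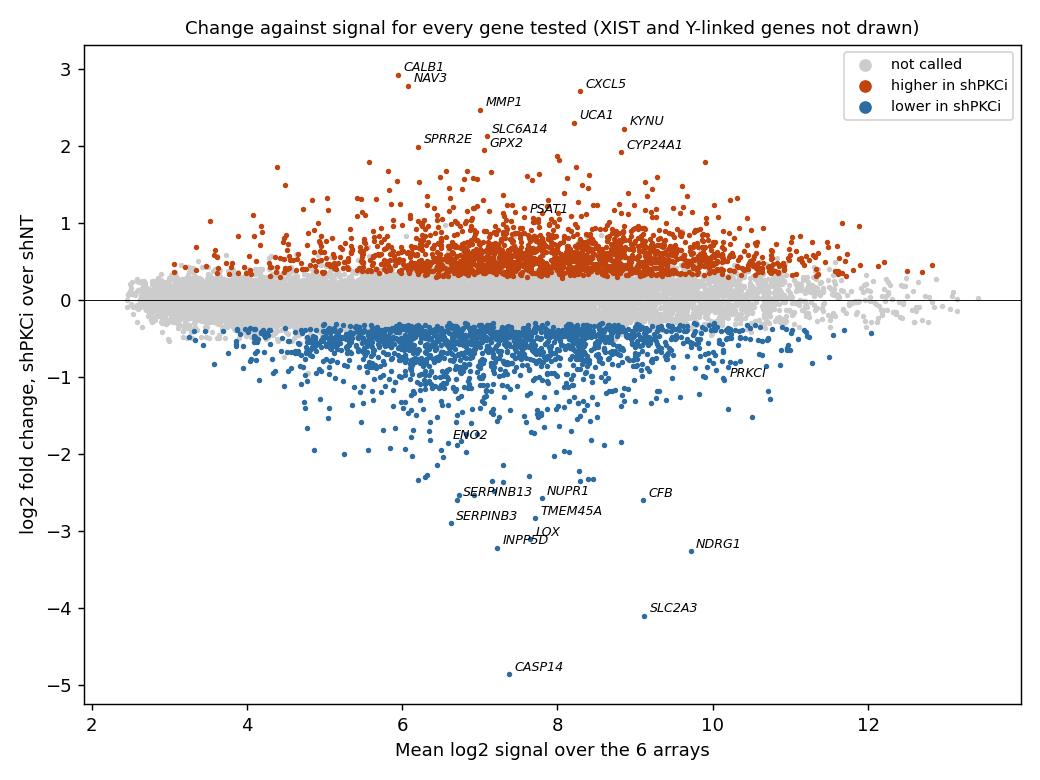
Log2 fold change of shPKCi over shNT (vertical axis) against mean log2 signal over the 6 arrays (horizontal axis), 1 point per gene, coloured where the adjusted p was under 0.05, with XIST and Y-linked genes not drawn. The 1758 higher and 1648 lower genes lie on both sides of 0, and CASP14 at -4.87 and SLC2A3 at -4.10 lie farthest below it.

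Of the 22 gene lists fixed before the data were examined, 7 were higher and 5 lower in shPKCi relative to other genes (limma camera with a preset correlation between genes, adjusted p under 0.05). Hypoxia, p53 target, glycolysis, basal epithelial and mesenchymal genes were the lower lists. The higher lists were cell cycle, NF-kappaB and inflammatory cytokine, aminoacyl-tRNA synthetase, sterol and fatty acid synthesis, endoplasmic reticulum chaperone, interferon response and methionine cycle genes. With the correlation estimated from the data, 5 lists passed: hypoxia, p53 targets, NF-kappaB, sterol and fatty acid synthesis, and endoplasmic reticulum chaperones. The other 9 ways of splitting the 6 arrays into groups of 3 gave up to 10 lists past the threshold with the preset correlation. Those splits held both lines on each side in unequal numbers, so that part of the line difference remained. The 10 is therefore not a rate expected by chance.

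**Figure D2:**
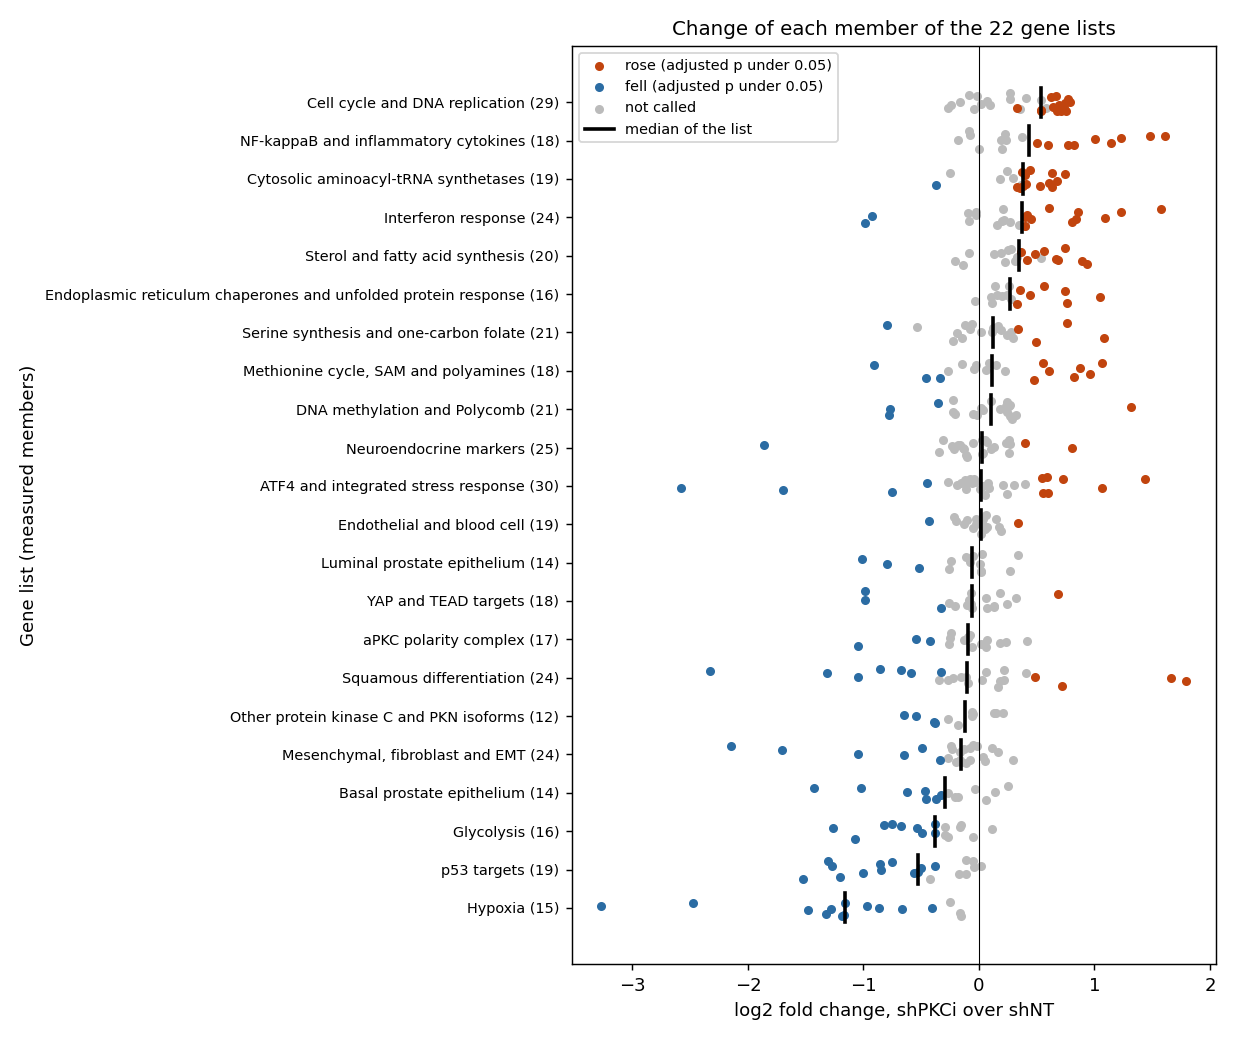
Log2 fold change of shPKCi over shNT (horizontal axis) of each measured member of the 22 gene lists (rows, with the number measured), coloured where the gene rose or fell at an adjusted p under 0.05, with a black bar at each list's median. The hypoxia list has its median at -1.16 and the cell cycle list at 0.53.

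Among the genes of serine synthesis and one-carbon folate metabolism, PSAT1 rose and the enzymes before and after it in the pathway did not pass the test. PSAT1, the aminotransferase of serine synthesis, was 2.12-fold higher, at 7.03 ± 0.0042 log2 units in shNT and 8.11 ± 0.04 in shPKCi (SD, n = 3; adjusted p = 5.21e-05). PHGDH, which encodes the first enzyme of the pathway, had a log2 fold change of -0.06 (SE 0.13, adjusted p = 0.813), and PSPH, which encodes the last, had 0.02 (SE 0.13, adjusted p = 0.955). A dimmer PSPH probe set fell by 0.95 (adjusted p = 0.0062 over all probe sets). The mitochondrial folate carrier gene SLC25A32 rose by 0.77, the glutamine and serine transporter gene SLC1A5 by 0.49 and the formyltransferase gene MTFMT by 0.34. TYMS, which encodes thymidylate synthase, fell by 0.79, or 1.73-fold. The serine hydroxymethyltransferase genes SHMT1 and SHMT2 had log2 fold changes of 0.24 (adjusted p = 0.341) and 0.28 (adjusted p = 0.0827). Those of the folate enzyme genes MTHFD1, MTHFD2 and MTHFD1L were 0.17, 0.13 and -0.22, and none of these 3 passed.

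Of 21 measured members of that list, 4 rose, 1 fell and 16 did not pass, with the same 4 and 1 when adjusted over the list alone. The median was 0.13 and the list did not pass camera (adjusted p = 0.156, and adjusted p = 0.245 with an estimated correlation). The series title names this pathway, so that the list is not independent evidence of its direction. The rise of MTFMT did not pass without any single array except shNT replicate 1, with adjusted p from 0.0641 to 0.144 in the other 5 fits. SHMT2 passed with each array centred on its median (adjusted p = 0.0395) and among genes above the median signal (0.0338). It also passed with a trended robust variance (0.0439) and with array weights (0.0493). SLC1A5 did not pass with the mean of its probe sets (adjusted p = 0.0706).

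**Figure D3:**
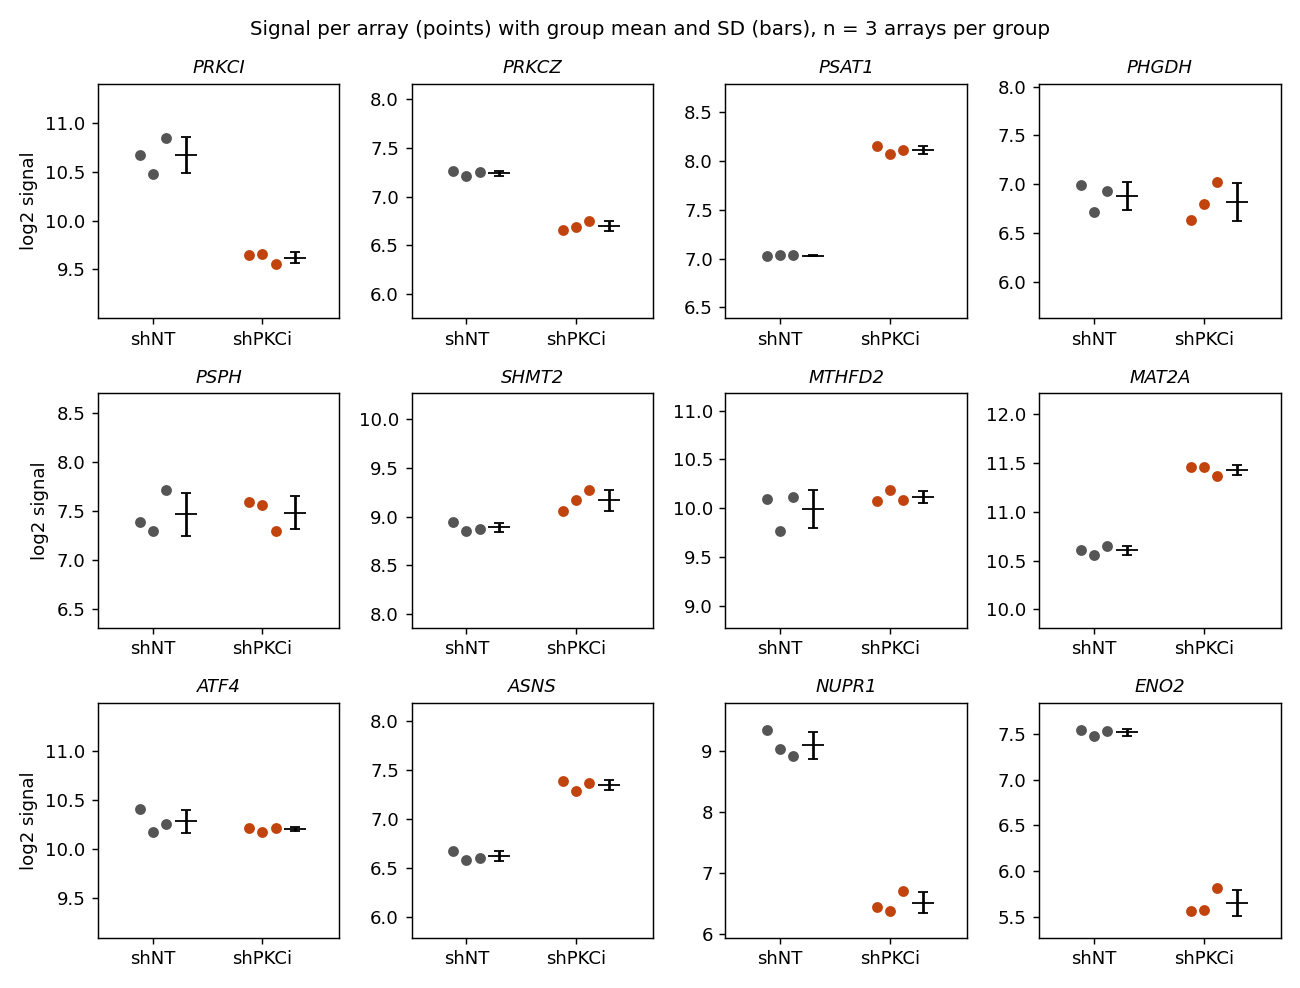
Log2 signal (vertical axes) of 12 genes in the 3 shNT and 3 shPKCi arrays, 1 point per array, with the group mean and SD as a bar beside the points; every panel has its own range. PSAT1 lies near 7.03 in shNT and 8.11 in shPKCi, whereas the PHGDH and PSPH points of the groups overlap.

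Several genes that make S-adenosylmethionine and polyamines rose. MAT2A, encoding the synthetase of S-adenosylmethionine, was 1.77-fold higher (10.61 ± 0.04 in shNT and 11.43 ± 0.06 in shPKCi, SD, n = 3; adjusted p = 0.000323). ODC1, the entry enzyme gene of polyamine synthesis, rose by 0.96, the spermidine synthase gene SRM by 0.87 and the transsulfuration gene CTH by 1.06. NNMT, which encodes a methyltransferase that consumes S-adenosylmethionine, fell by 0.91. AHCY had a log2 fold change of 0.15 (adjusted p = 0.453). Of 18 measured members of the methionine cycle list, 7 rose and 3 fell, and the numbers were 7 and 3 adjusted over the list alone. The list passed camera (adjusted p = 0.0346) but not with an estimated correlation (adjusted p = 0.187). It also lost the call without shNT replicate 3 (adjusted p = 0.0522), without shPKCi replicate 2 (0.0627) and after cyclic loess between arrays (0.116).

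DNA methylation and Polycomb genes did not pass as a list. DNMT1 had a log2 fold change of 0.26 (SE 0.09, adjusted p = 0.0857), DNMT3A of -0.22 (adjusted p = 0.135) and DNMT3B of 0.23 (adjusted p = 0.174). Of 21 measured members, TDG rose by 1.32, and TET1, EZH1 and TET2 fell by 0.77, 0.77 and 0.35; these 4 were named after their values were seen. TDG and the TET genes encode enzymes of active DNA demethylation. The same 1 and 3 genes passed adjusted over the list alone, and camera gave an adjusted p of 0.54. Without shNT replicate 2, 3 members rose and 3 fell. DNMT1 passed without shNT replicate 2 (adjusted p = 0.027) and with each array centred on its median (0.0357). It also passed among genes above the median signal (0.0336), with a trended robust variance (0.0456) and with array weights (0.0162).

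Members of the ATF4 and integrated stress response list that passed the test went both ways. SLC7A11, the cystine transporter gene, rose by 1.44 and CTH by 1.06, and the asparagine synthetase gene ASNS was 1.66-fold higher (6.62 ± 0.05 in shNT and 7.35 ± 0.05 in shPKCi, SD, n = 3; adjusted p = 0.000616). NUPR1 fell by 2.58, and the lipoprotein receptor gene VLDLR was 3.25-fold lower. The transcript of ATF4 itself had a log2 fold change of -0.08 (SE 0.10, adjusted p = 0.671), and the ATF4 protein was not measured. Of 30 measured members, 7 rose and 4 fell, and 8 rose and 4 fell adjusted over the list alone. The list had a median of 0.02 and did not pass camera (adjusted p = 0.342, and adjusted p = 0.484 with an estimated correlation).

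Genes of cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose in 13 of 19 measured members. WARS1 was higher by 0.74, YARS1 by 0.68, MARS1 by 0.63 and TARS1 by 0.63 on the log2 scale, with adjusted p between 0.00061 and 0.00257. SARS1 was the 1 member that fell, by 0.37, and it was named after its value was seen. Adjusted over the list alone, 16 rose and 2 fell. The list passed camera (adjusted p = 7.44e-07), and its adjusted p was 0.167 with an estimated correlation. Its mean in shNT replicate 2 lay at -0.28 relative to the mean of the 6 arrays, against -0.13 and -0.15 in the other shNT arrays. Without that array, 12 members rose and 1 fell. In the 6 fits without 1 array, camera with the preset correlation gave an adjusted p of at most 1.17e-05.

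Neuroendocrine markers did not pass as a list, and 3 of the best known were dim. CHGA, which encodes chromogranin A, had a log2 fold change of -0.14 (adjusted p = 0.611), SYP, which encodes synaptophysin, of 0.23 (adjusted p = 0.321) and NCAM1 of -0.10 (adjusted p = 0.644). CHGA lay at the 20.1th percentile of signal among all genes, SYP at the 30.4th and NCAM1 at the 14.8th. ENO2, the gene of neuron-specific enolase and a glycolytic enzyme, was 3.63-fold lower, at 7.52 ± 0.04 in shNT and 5.66 ± 0.14 in shPKCi (SD, n = 3; adjusted p = 6.83e-06). AURKA, a mitotic kinase gene, rose by 0.81, and the transcription factor gene FOXA2 by 0.40. SOX2 had a log2 fold change of -0.34 (adjusted p = 0.0769) and SNAP25 of -0.31 (adjusted p = 0.114). Of 25 measured members, 2 rose and 1 fell, with the same 2 and 1 adjusted over the list alone. The median was 0.03 and the mean -0.05, and camera, downward in direction, gave an adjusted p of 0.927 (adjusted p = 0.971 with an estimated correlation). FOXA2 did not pass without shNT replicate 1 (adjusted p = 0.0522), shPKCi replicate 2 (0.0939) or shPKCi replicate 3 (0.0557). The series title names the neuroendocrine state, so that the list is not independent evidence of its direction.

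Of 14 measured genes of the basal prostate epithelium list, 7 fell and none rose. The desmosomal cadherin genes DSG3 and DSC3 fell by 1.42 and 1.02 (adjusted p = 1.79e-05 and 0.000416), and the P-cadherin gene CDH3 and the integrin gene ITGB4 by 0.62 and 0.45. Adjusted over the list alone, 1 rose and 8 fell, and without shNT replicate 2, 1 rose and 6 fell. The list's median was -0.30 (camera adjusted p = 0.00104, and adjusted p = 0.0753 with an estimated correlation). The fall of ITGB4 did not pass without shPKCi replicate 2 (adjusted p = 0.0839) or shPKCi replicate 3 (0.0575). TP63 and KRT17 of this list were not analysed here.

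Of 24 measured genes of the mesenchymal, fibroblast and EMT list, 6 fell, none rose and 18 did not pass. The smooth muscle actin gene ACTA2 fell by 2.15 (adjusted p = 6.54e-06), the transgelin gene TAGLN by 1.71, the fibroblast activation protein gene FAP by 1.05 and the osteonectin gene SPARC by 0.65. The numbers that rose and fell were the same adjusted over the list alone. Camera gave an adjusted p of 0.00178, and an adjusted p of 0.182 with an estimated correlation. In shNT replicate 2 the list lay 0.26 above the mean of the 6 arrays, against 0.12 and 0.10 in the other shNT arrays. Without that array, 5 members fell and 0 rose. In the 6 fits without 1 array, camera with the preset correlation gave an adjusted p of at most 0.0143.

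Other markers of cell type gave no list past the threshold, and the members named for them were chosen after their values were seen. Of 14 luminal epithelial genes, ACP3, DPP4 and KRT19 fell by 1.02, 0.80 and 0.52 and none rose (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.244). In the fit without shNT replicate 2, 2 of the 14 rose and 3 fell. Squamous differentiation genes went both ways: SPRR2A and KLK6 rose by 1.80 and 1.66, while the transglutaminase gene TGM1 and KRT16 fell by 2.33 and 1.32. Of its 24 members 4 rose and 7 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.339). Endothelial and blood cell markers numbered 19, of which CD3D rose by 0.34 and KDR fell by 0.43, also when adjusted over the list alone (camera adjusted p = 0.96).

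Hypoxia genes showed the lowest median of any list, at -1.16. NDRG1 fell by 3.27 (adjusted p = 6.44e-07), the prolyl hydroxylase gene EGLN3 by 2.48, the lipase inhibitor gene ANGPTL4 by 1.32 and the mitophagy receptor gene BNIP3L by 1.28. None of 15 measured members rose and 12 fell, also when adjusted over the list alone. The list passed camera (adjusted p = 3.69e-13), and it did so with an estimated correlation (adjusted p = 0.0318). Its mean lay between 0.45 and 0.62 above the mean of the 6 arrays in the shNT arrays, the lowest being shNT replicate 2, and between -0.58 and -0.55 in the shPKCi arrays. Glycolysis genes fell in 9 of 16 measured members and rose in none, and 12 fell adjusted over the list alone. The glucose transporter gene SLC2A1 fell by 1.26 (adjusted p = 0.000139), the aldolase gene ALDOC by 1.08, the hexokinase gene HK2 by 0.82 and PFKFB3 by 0.75. This list passed camera (adjusted p = 9.81e-07) but not with an estimated correlation (adjusted p = 0.138).

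Several p53 target genes fell and several genes of the cell cycle rose. Among p53 targets, the ribonucleotide reductase gene RRM2B fell by 1.52, the DNA repair gene DDB2 by 1.31, TP53INP1 by 1.27 and the polymerase gene POLH by 1.21, with adjusted p from 2.39e-05 to 0.000175. None of 19 measured targets rose and 12 fell, and 13 fell adjusted over the list alone (camera adjusted p = 1.07e-08, and adjusted p = 0.0318 with an estimated correlation). Among cell cycle genes, the mitotic transcription factor gene FOXM1 rose by 0.75, the replication licensing gene CDC6 by 0.75, CDC20 by 0.70 and the mitotic kinase gene PLK1 by 0.68. FOXM1 had a mean of 8.38 ± 0.05 in shNT and 9.13 ± 0.01 in shPKCi (SD, n = 3; adjusted p = 0.000492). None of 29 measured members fell and 14 rose, and 18 rose adjusted over the list alone. The cell cycle list passed camera (adjusted p = 7.44e-07), and its adjusted p was 0.182 with an estimated correlation. Its mean in shNT replicate 2 lay at -0.36 relative to the mean of the 6 arrays, against -0.10 and -0.11 in the other shNT arrays; without that array 15 members rose and 1 fell.

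**Figure D4:**
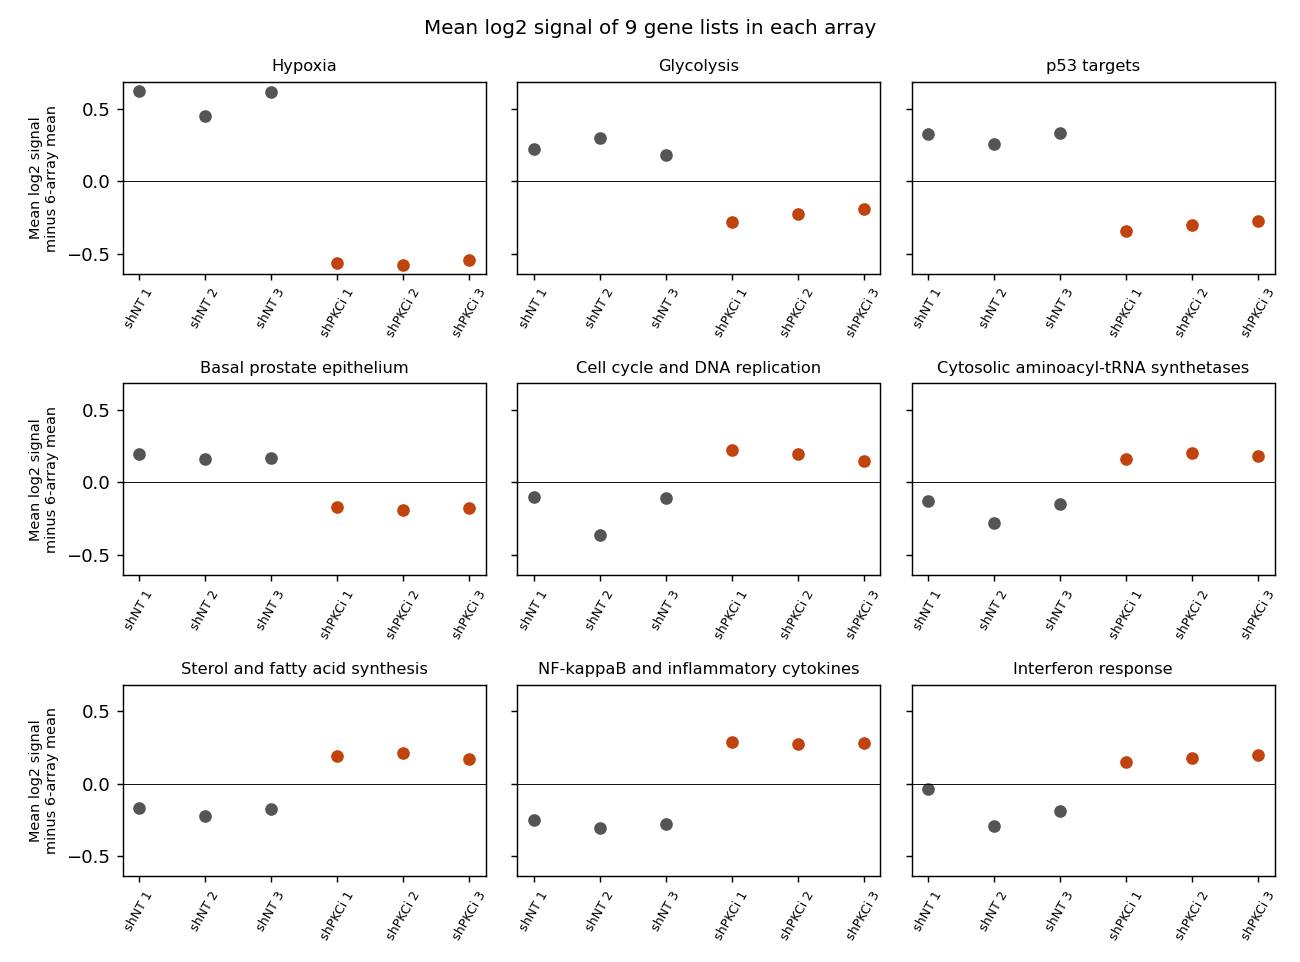
Mean log2 signal of 9 gene lists in each of the 6 arrays (horizontal axis), relative to the mean of the 6 arrays (vertical axis), with shNT arrays in grey and shPKCi arrays in orange. In every panel the 3 shPKCi arrays lie on 1 side of the 3 shNT arrays, with the hypoxia list between 0.45 and 0.62 in shNT and between -0.58 and -0.55 in shPKCi.

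Several inflammatory and interferon-response transcripts rose. In the NF-kappaB list, CXCL2 rose by 1.61, the cytokine gene IL6 by 1.48, CXCL8 by 1.23 and IL1B by 1.14, with adjusted p from 3.33e-05 to 0.000122. None of 18 measured members fell and 9 rose, and 10 rose adjusted over the list alone (camera adjusted p = 7.44e-07, and adjusted p = 0.0318 with an estimated correlation). In the interferon list, IFI44 rose by 1.57, IFIT1 by 1.23, MX1 by 0.86 and IFIT3 by 0.84. Of 24 measured members 11 rose and 2 fell, and 13 rose and 2 fell adjusted over the list alone. The members that fell, named after their values were seen, were the chemokine genes CXCL10 and CXCL11, by 0.92 and 0.98. The interferon list passed camera (adjusted p = 3.95e-05), and its adjusted p was 0.167 with an estimated correlation. Its mean in shNT replicate 2 was -0.29, against -0.04 and -0.19 in the other shNT arrays. Without that array, 11 members rose and 2 fell. In the 6 fits without 1 array, camera with the preset correlation gave an adjusted p of at most 0.000582.

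Several lipid synthesis and protein folding genes rose too. Of 20 measured sterol and fatty acid synthesis genes 9 rose and none fell, and 13 rose adjusted over the list alone. HMGCS1, an early enzyme gene of cholesterol synthesis, rose by 0.94, the sterol sensor gene INSIG1 by 0.89, the fatty acid synthase gene FASN by 0.75 and ACLY by 0.69 (camera adjusted p = 1.99e-06, and adjusted p = 0.0318 with an estimated correlation). Of 16 endoplasmic reticulum chaperone genes 7 rose and none fell, and 9 rose adjusted over the list alone. SDF2L1 rose by 1.04, the chaperone gene HSPA5 by 0.76, DNAJC3 by 0.74 and DNAJB11 by 0.56 (camera adjusted p = 6.85e-06, and adjusted p = 0.0318 with an estimated correlation).

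Of 17 atypical PKC polarity genes, PRKCI, PRKCZ and PATJ fell, PATJ by 0.42, and none rose, also when adjusted over the list alone (camera adjusted p = 0.189). Without shNT replicate 2, 5 of the 17 fell. Of 12 further kinase C and PKN genes, PRKCA fell by 0.64, PRKCZ by 0.54, PRKCQ by 0.39 and PRKD1 by 0.38, also when adjusted over the list alone. That list did not pass camera (adjusted p = 0.0677, and adjusted p = 0.281 with an estimated correlation) but passed with the preset correlation without shNT replicate 2 (adjusted p = 0.0335). Of 18 YAP and TEAD targets, NT5E rose by 0.68, while CCN2, CRIM1 and AXL fell by 0.98, 0.99 and 0.32 (2 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.616). Apart from PRKCI and PRKCZ, the members named from these 3 lists were chosen after their values were seen.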

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

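The tests of the within-group spread of the hypoxia list, of culture density, of growth state and of a swapped label were chosen only after the results were seen. Fits without shNT replicate 2 were planned, but the one of the hypoxia list was taken as a test of that array's part only after its result was seen.

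Probe sets outside the gene comparison also differed between the lines. Of 11775 probe sets not listed with a gene, 189 were higher in shPKCi than in shNT and 108 lower (limma, adjusted p under 0.05 over all probe sets). Of 1388 probe sets with several gene symbols, 62 were higher and 53 lower. These are listed because the comparison did not use them, not for an excess: 2.52% and 8.29% of these probe sets passed, against 10.99% of those with 1 gene symbol. The median log2 signal was 4.15 in the probe sets not listed with a gene and 6.13 in those with 1 symbol.

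The hypoxia and glycolysis lists were lower in shPKCi. Of the glycolysis members 9 of 16 fell, and that list did not pass camera with an estimated correlation (adjusted p = 0.138). In shNT replicate 2 the hypoxia mean lay nearest the shPKCi arrays (0.45, against 0.62 and 0.61 in the other shNT arrays). This argues against that array as the source of the hypoxia fall. Leaving it out could only widen the difference, so that the camera adjusted p of 1.85e-13 without it is no further test. The hypoxia median lay at percentile 0 of random lists matched on signal, which argues against signal level. The difference between the groups was 11.4 times the larger within-group SD of the list mean. A difference in density or oxygen between the cultures of the lines cannot be told apart from an effect of PRKCI loss: the glycolysis median of -0.38 is allowed by both, and each line was grown in its own cultures. An effect of the hairpin sequence on other transcripts stays open, since 1 hairpin label was used.

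The p53 target list was lower and the cell cycle list higher in shPKCi, with 12 of 19 targets falling and 14 of 29 cell cycle genes rising. The cell cycle list did not pass camera with an estimated correlation (adjusted p = 0.182). Without shNT replicate 2 the camera adjusted p was 3.06e-09 for the p53 list and 2.11e-05 for the cell cycle list. The second value argues against that array as the whole source of the cell cycle rise. In the p53 list that array lay nearest the shPKCi arrays (0.26, against 0.33 and 0.33 in the other shNT arrays), so that leaving it out could only widen the difference. The p53 and cell cycle medians lay at percentiles 0 and 100 of random lists matched on signal, which argues against signal level. A difference in growth state between the cultures cannot be told apart from an effect of PRKCI loss, since the cell cycle median of 0.53 is allowed by both and each line was grown in its own cultures.

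The array of shNT replicate 2 stood apart from the others. A smooth trend with signal, as a compressed range would leave, explained 15.9% of the variance of its deviation, and after its removal the remaining SD was 1.42 times the largest of the other 5 arrays, which argues against compression as the whole source. Its PRKCI signal lay 14.7 SDs of the shPKCi arrays above the highest of them, which argues against a swapped label. What set this array apart stays open, and no biological explanation was tested.

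With 10 ways of splitting the 6 arrays, no share under 0.05 can be reached, so chance cannot be tested at that level. The real split gave 3406 genes and the highest other split 0, so that 1 split gave as many. For gene lists the real split gave 12 and the highest other split 10, so that 1 split again gave as many. The other splits mixed the lines unevenly, which left part of the line difference in the lists and widened the spread of each gene. Neither the 0 nor the 10 is therefore a rate expected by chance.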

How the results depend on the processing

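Removal of each array's intensity trend and lists without shared genes were chosen only after the data were seen. Under the 10 of 18 alternatives that give it a value, and in 6 fits without 1 array, PRKCI stayed lower, from -1.17 to -0.96. Of the values of named genes under the alternatives, 953 kept their side of the threshold, 4 lost and 8 gained a call and 2 reversed. For lists the numbers were 291, 11, 6 and 0. Without 1 array, 577 gene values were kept, 10 lost and 1 gained, and 129 list values were kept, 2 lost and 1 gained. The kept values include 9 of genes and 12 of lists, counted per setting, whose direction turned while they passed in neither fit. Under the filters on signal, 10 named genes had no value. The reversed result was PSPH, at -0.47 with the mean of its probe sets (adjusted p = 0.0421) and -0.95 with the probe set of largest interquartile range; the choice of probe set is the cause, since its probe sets differ.

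Genes higher and lower numbered 88 and 180 with treat against a fold of 1.5, 756 and 788 with a fold of at least 1.5, and 870 and 902 at an adjusted p of 0.01, each a stricter threshold. Without 1 array they ran from 997 to 1935 and from 1048 to 1959, lowest without shPKCi replicate 2; 1072 and 1057 without shPKCi replicate 1 and 1165 higher without shPKCi replicate 3 were also over 1.5 times fewer. Of 3406 and 3894 genes past the threshold with all arrays and without shNT replicate 2, 3163 were shared. With estimated correlation 3 lists were higher and 2 lower, and fry gave 9 lower, a test that does not compare with other genes. The methionine list had adjusted p of 0.116 after cyclic loess, 0.187 with estimated correlation, 0.139 on ranks, 0.112 without shared genes and 0.138 after trend removal, and ranged from 0.0217 to 0.0627 without 1 array, past the threshold except without shNT replicate 3 (0.0522) and shPKCi replicate 2; the cause was not tested. The serine list gained a call under fry (0.0127).

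With a replicate block, 1537 genes were higher and 1441 lower, and of the named genes and lists MTFMT alone changed its call. Same-numbered arrays had deviations correlated at 0.12, -0.06 and -0.18, and not every array correlated best with its own number. These values gave no sign that the numbers pair the samples, but 3 arrays per group cannot exclude it. Signal over background could not be judged without detection calls, which limits what can be said of dim genes.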

Other observations

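The gene lists of this part were chosen only after the data were seen, and so were their tests; they were adjusted over the 17 added lists. Members named here were chosen by their values, and each adjusted p is that of camera for the whole list.

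Of 27 measured genes of the ribosome biogenesis list, 24 rose in shPKCi and none fell. The list passed camera, but its adjusted p was 0.198 with an estimated correlation. LYAR rose by 1.54 (SE 0.12), the RNA polymerase I subunit gene POLR1B by 1.19 (SE 0.10), UTP20 by 1.11 (SE 0.11) and the methyltransferase gene NOP2 by 1.10 (SE 0.09). The mitochondrial ribosomal protein genes rose in 28 of 73 members and fell in none (camera adjusted p = 8.6e-12, and adjusted p = 0.198 with an estimated correlation). Proteasome subunit genes rose in 14 of 45 members and PSME1 fell (adjusted p = 5.05e-07, and adjusted p = 0.498 with an estimated correlation). Of 64 genes matched by symbol as cytosolic ribosomal proteins, 3 rose and 6 fell. The match also took in like-named relatives of these genes, of which RPL7L1 and RPL22L1 rose and RPS27L fell. That list did not pass camera (adjusted p = 0.0645, downward), but passed without shNT replicate 2 (adjusted p = 0.00106); with all arrays and an estimated correlation its adjusted p was 0.678. Small nucleolar RNAs rose in 32 and fell in 9 of 176 (adjusted p = 0.0116, and adjusted p = 0.498 with an estimated correlation), and of 33 complex I subunit genes NDUFV1 alone passed and fell (adjusted p = 0.663).

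Of the other families defined by symbol pattern, clade B serpins, small proline-rich proteins, integrins and collagens passed camera, none of them with an estimated correlation. SERPINB3, SERPINB13 and SPRR2E, already seen among the largest changes, were kept in their lists. The serpin and small proline-rich calls are therefore not independent of those genes. Clade B serpin genes fell in 5 and rose in 2 of 11 members, where SERPINB4 fell by 2.03 and SERPINB1 rose by 0.93 (adjusted p = 0.00514, and adjusted p = 0.198 with an estimated correlation). Small proline-rich protein genes rose in 6 of 10, and SPRR1A fell by 0.86 (adjusted p = 0.00621, and adjusted p = 0.198 with an estimated correlation). Integrin genes fell in 6 of 25 and collagen genes in 4 of 43, with none rising (adjusted p = 0.0116 and 0.0329, and adjusted p = 0.498 and 0.678 with an estimated correlation). Collagens did not pass without shNT replicate 2 (adjusted p = 0.248). ITGB6 fell by 0.92, ITGAV by 0.84 and COL4A2 by 0.55. CXC chemokine genes rose in 5 and fell in 3 of 14 (adjusted p = 0.0636), where CXCL5 and CXCL6 rose by 2.71 and 1.81 and CXCL14 fell by 0.75. Keratins rose in 2 and fell in 6 of 48 (adjusted p = 0.284), matrix metalloproteinases in 2 and 2 of 22 (adjusted p = 0.823) and kallikreins in 1 and 1 of 15 (adjusted p = 0.89). Of 340 olfactory receptor genes, dim in these cells, 1 rose and none fell (adjusted p = 0.979).

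The rise of aminoacyl-tRNA synthetase genes may be part of a wider rise of genes of protein synthesis. The ribosome biogenesis list, tested for this, was higher (camera adjusted p = 2.29e-18), with an adjusted p of 0.198 with an estimated correlation, so that the hypothesis rests on the preset correlation. Of 64 genes matched by symbol as cytosolic ribosomal proteins, RPL7L1, RPL22L1 and RPS27L included, 3 rose, 6 fell and the others did not pass. That list did not pass camera (adjusted p = 0.0645, downward, and adjusted p = 0.678 with an estimated correlation), but passed without shNT replicate 2 (adjusted p = 0.00106).

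A group-wide fall of complement genes was tested after CFB, C1R and SERPING1 were seen among the largest falls. Without these 3, the list was lower (camera adjusted p = 0.0245, and adjusted p = 0.198 with an estimated correlation). Of its 16 members 4 fell, C1S by 2.28, C5 by 0.83, CD59 by 0.39 and CLU by 0.37, and the list's median was only -0.091. C1S was kept, although its fall was close in size to those of the 3 genes left out. The list was not tested without C1S, so that this call cannot tell a group-wide fall from large falls of a few genes. A shared rise of NRF2 targets, looked for because SLC7A11 and GPX2 rose, did not pass camera without those 2 genes (adjusted p = 0.122), which does not exclude it. Of 24 members 6 rose, TXNRD1 by 1.60 and ME1 by 0.90 among them, and 2 fell, AKR1C2 by 0.39 and FTL by 0.30.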
